A study of Mus musculus with 36 samples.

How the data were processed

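RNA-seq libraries of hypothalamus from 19 mice and Cas9 ChIP-seq of hypothalamus and Neuro2A cells were used. Per the labels' protocols, RNA was isolated with RNeasy columns and made into libraries with Nugen Ovation and Nextera XT kits, which carry no stated strand information. ChIP used formaldehyde-fixed tissue, the Low cell ChIP kit, an S. pyogenes Cas9 polyclonal or an S. aureus Cas9 monoclonal antibody, and ThruPLEX libraries. Per the submitters' processing notes, CASAVA 1.8, STAR 2.5.2b, MACS2 2.1.1.20160309 and DESeq2 1.16.1 were used, without their roles, and the genome build is given as mm9. The coordinates in the tables lie in GRCm38 instead: 20223 genes matched the RefSeq annotation of that assembly by identifier, and 99.9% of them overlapped their matched gene, so positions are given in GRCm38. The labels of the Neuro2A libraries also carry a mouse genotype, strain and age, which were not used here.

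The gene table held 22447 genes. Per the file headers, the authors deposited a normalized count for each gene and library, a mean of these counts over all libraries, and variance-stabilized values on a log2 scale. The low values of each library were whole multiples of 1 step, so the deposited normalized counts are read counts divided by 1 factor per library and rounded to 1 decimal. Dividing by that step gave whole reads, within 0.0505 of a normalized count, for at least 99.8% of the genes in each library, and the recovered totals ran from 14.1 to 84.8 M reads. The authors' stabilized log2 values are not a function of the normalized counts alone, and the further correction is not stated. Per the file headers the table also holds the authors' log2 fold changes with an unadjusted p-value and a false discovery rate for 3 comparisons, whose model is not stated, and the percent GC of each gene, an annotation that was not used here. The peak lists, 6 in all, hold 1 list per sgRNA, antibody and tissue or cell line. Per the file headers the authors gave the pileup signal at the summit, a fold enrichment over background as a ratio, and a -log10 q-value for each peak. How replicates were combined and which control was used is not given in the sources used here. ChIP libraries without an sgRNA and input libraries were not analysed here.

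The planned test assumed raw counts (edgeR). Because the table holds normalized counts, the alternative planned for that unit was used: limma 3.58.1 with a trended prior on log2(normalized count + 1), for the 20505 genes with a mean of at least 1, with sex as covariate and all 19 libraries in 1 fit, in R 4.3.3. Folds are on that scale, so the added 1 shrinks them for genes near 0. Adjustment was by Benjamini and Hochberg at 0.05 over all genes tested, 6 comparisons being made between the 4 groups. Libraries were taken as separate animals as far as the labels show. Sim1 and 14 genes fixed for naming were also adjusted over the list alone and tested with two-sided exact permutation tests of normalized counts, also in R. Gene lists (29) were tested with camera in limma at its preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. With the estimated correlation 0 lists were called in all 6 comparisons, and fry called 0 by direction and, among its mixed tests, 1 (interferon genes with the enhancer sgRNA). Each list call was repeated without each library in turn. Where the text says that members of a list were higher or lower, it gives signs of fold changes, and only members said to pass are calls.

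Gene lists, the naming rule and the settings listed in the next paragraph were fixed before the data were examined. The rule names Sim1, genes past the threshold (at most 10 in each direction), up to 4 members of a list by smallest p, and Oxt, Avp, Crh, Trh, Otp, Arnt2, Sim2, Pou3f2, Mc4r, Pomc, Agrp, Npy, Lepr and Bdnf. For ChIP it names every peak within 1 Mb of Sim1 and the 5 peaks of highest -log10 q-value in each list. For checks of sex it names Xist, Ddx3y, Kdm5d, Eif2s3y and Uty. Chosen after the data were seen were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, scaling of these by TMM, the stabilized values, a covariate for the share of reads on Gm42418, and a fit without 4 libraries that stood apart (Sim1 heterozygous F_4, wild type F_2, promoter sgRNA F_5 and M_3). That fit kept Sim1 heterozygous F_3, which stood apart in ribosomal protein genes (1.28 above the mean of all libraries, log2). Lists of reactive glial, liver, midbrain dopamine neuron and pineal genes, the limit of 4 months between age classes, age, meningeal and blood genes as covariates of the reactive glial list and all settings of the ChIP mixing test were also chosen after the data were seen. Limma, edgeR and DESeq2 were tested on simulated data of the Sim1 heterozygous and wild-type libraries with 100 genes changed 2-fold and 100 changed 4-fold, all drawn from genes with a mean of at least 50, so recovery at lower means was not measured. They recovered 72, 72 and 83 of the 2-fold and 99, 99 and 99 of the 4-fold changes, with 6, 5 and 28 false calls over 20227, 17147 and 20505 genes tested. Each gene was simulated independently, without the differences in tissue and age met in the real libraries. These numbers therefore do not measure recovery in the real fits, where a lack of calls does not show a lack of such changes.

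Similarity of the sgRNA responses was set against 100 simulations of unchanged groups with shared controls and against the 6 ways to divide the 4 controls between the comparisons. Peaks were intersected with bedtools 2.31.1 at 1 bp or more. Tested genes within 100 kb of a peak were compared with all others by Fisher's exact test, two-sided (scipy 1.17.1, python 3.11.15). Regions around Sim1 and 2 loci often used for insertion were tested, and windows of 20 Mb across the genome scanned. Splits of the libraries into groups of the same sizes, at most 100 per comparison with the real grouping among them, were refitted. Settings fixed in advance were another pseudocount and filter, age, strain or a replicate block in the model, females alone, the compared groups alone, each library left out, stricter peak thresholds, other windows and other overlaps. Counts of peaks and folds come without depths, so no counting interval is given for them.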

Results

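RNA was sequenced from the hypothalamus of 19 mice in 4 groups, and DNA bound by Cas9 was sequenced from hypothalamus and from Neuro2A cells, a mouse neuroblastoma line. The RNA groups were 5 wild-type mice, 4 mice with 1 working copy of Sim1 (Sim1 heterozygous), 6 Sim1 heterozygous mice with a guide RNA for the Sim1 promoter (promoter sgRNA) and 4 Sim1 heterozygous mice with a guide RNA for a Sim1 enhancer (enhancer sgRNA). Sim1 encodes a transcription factor needed for neurons of the paraventricular nucleus, and CRISPR activation uses a Cas9 that does not cleave DNA to bring an activator to the guide's target. Ages ran from 3 to 9 months, 6 animals were male, and wild type F_2 and Sim1 heterozygous F_3 were B6 while all others were B6/FVB. Reads recovered from the normalized values numbered 32.1, 37.9, 28.1, 84.8 and 54.3 M in wild type F_1, F_2, F_3, F_4 and M_1, and 48.0, 25.2, 38.8 and 19.4 M in Sim1 heterozygous F_1, F_3, F_4 and M_1. They numbered 18.8, 14.1, 29.5, 18.6, 28.6 and 56.5 M in promoter sgRNA F_1, F_2, F_3, F_5, M_1 and M_3, and 29.0, 52.9, 14.6 and 29.2 M in enhancer sgRNA F_1, F_2, M_1 and M_3.

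Sim1 (ENSMUSG00000019913; chromosome 10, 50894754 to 50989152 in GRCm38) was measured in every library. Wild type F_1, F_2, F_3, F_4 and M_1 held 547, 485, 394, 305 and 381 normalized counts, a mean of 423 ± 94.6 (SD, n = 5). Sim1 heterozygous F_1, F_3, F_4 and M_1 held 329.9, 158, 121 and 236 normalized counts, a mean of 211 ± 92.6 (SD, n = 4). Promoter sgRNA F_1, F_2, F_3, F_5, M_1 and M_3 held 431, 190.1, 155, 227, 316 and 159.8 normalized counts, a mean of 246 ± 108 (SD, n = 6). Enhancer sgRNA F_1, F_2, M_1 and M_3 held 287, 353, 272 and 287 normalized counts, a mean of 299.9 ± 36.1 (SD, n = 4). The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty and the X-inactivation transcript Xist matched the labelled sex in all 19 libraries: Ddx3y lay between 1308 and 3315 normalized counts in males and at most at 2.5 in females.

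**Figure D1:**
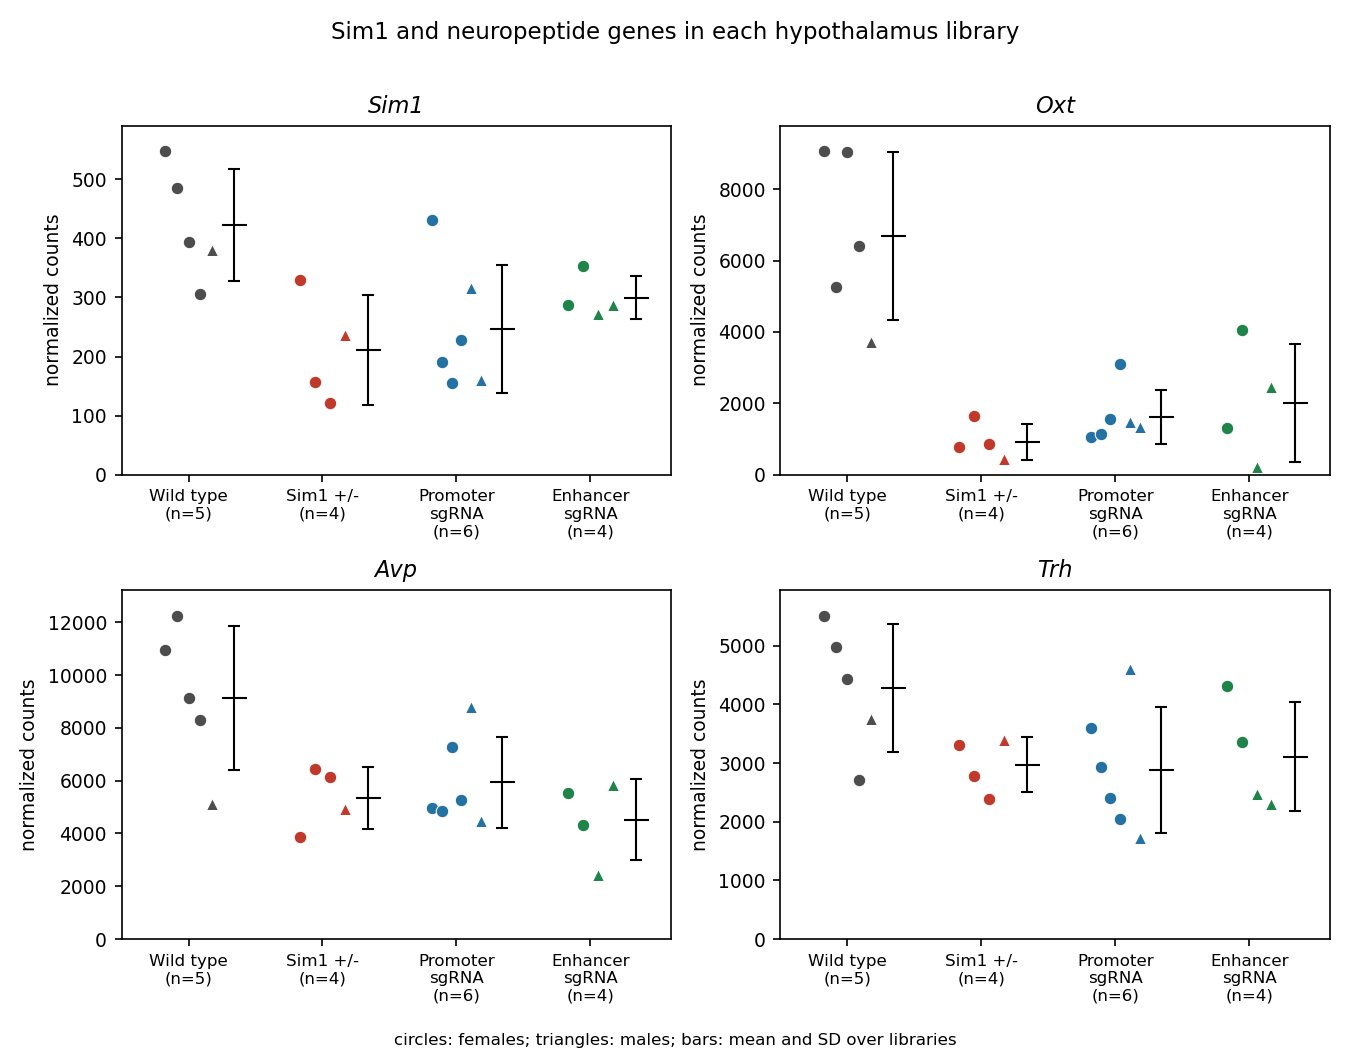
Normalized counts of Sim1, Oxt, Avp and Trh in each hypothalamus library by group (circles females, triangles males, bars mean and SD). Oxt averaged 6698 in wild type and 924 in the Sim1 heterozygous group, and Sim1 423 and 211.

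The comparison of Sim1 heterozygous with wild-type hypothalamus asks what the loss of 1 Sim1 copy does there. Sim1 stood at 49.9% of the wild-type mean in the Sim1 heterozygous group. Oxt, which encodes oxytocin, a peptide of paraventricular and supraoptic neurons, stood at 13.8% of the wild-type mean, 924 ± 505 (SD, n = 4) against 6698 ± 2357 (SD, n = 5) normalized counts, and no Sim1 heterozygous library reached the lowest wild-type library. Avp, the vasopressin gene, stood at 58.5%, 5345 ± 1170 (SD, n = 4) against 9141 ± 2732 (SD, n = 5), and Trh, the thyrotropin-releasing hormone gene, averaged 2968 ± 470.0 (SD, n = 4) against 4277 ± 1091 (SD, n = 5). Npy, an appetite-raising peptide of the arcuate nucleus, went the other way, at 175% of wild type (1006 ± 418, SD, n = 4, against 577 ± 46.7, SD, n = 5). Crh, the corticotropin-releasing hormone gene, averaged 190.0 ± 97.5 (SD, n = 4) against 219 ± 81.1 (SD, n = 5).

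In limma over all 20505 genes tested, the log2 fold change was -1.07 for Sim1 (SE 0.298, adjusted p = 0.868) and -2.89 for Oxt (SE 0.527, adjusted p = 0.265). Adjusted over the list alone, meaning Sim1 and the 14 genes fixed for naming, limma's p was 0.0139 for Sim1, 0.000387 for Oxt, 0.0601 for Avp, 0.139 for Npy and 0.211 for Trh. The two-sided exact permutation p was 0.0238 for Sim1, 0.0159 for Oxt, 0.0476 for Avp and 0.0476 for Npy over 126 splits, and 0.179 for each of them once adjusted over Sim1 and the 14 genes. Of the transcription factors and partners of the same lineage, Otp was at -0.16 (SE 0.347), Arnt2 at -0.02 (SE 0.129), Sim2 at 0.28 (SE 0.303) and Pou3f2 at -0.20 (SE 0.132) on the log2 scale. The arcuate peptide genes Pomc and Agrp were at 0.73 (SE 0.531) and 0.68 (SE 0.533), and the receptors and growth factor of feeding circuits at -0.03 for Mc4r (SE 0.225), -0.01 for Lepr (SE 0.347) and -0.07 for Bdnf (SE 0.214). Agrp overlaps another annotated gene on the same strand, and its counts are uncertain to that extent. Leaving out any 1 of the 19 libraries kept the log2 fold change of Sim1 between -1.33 and -0.83. Sim1's call in limma, adjusted over the list alone, ended without Sim1 heterozygous F_4 (adjusted p = 0.0758), without both B6 animals (0.0904) and without 4 libraries that stood apart (0.162), while Oxt's call stayed in every setting. Avp's p, adjusted over the list alone, fell under 0.05 without Sim1 heterozygous F_3 (0.0456), wild type M_1 (0.0167), promoter sgRNA F_2 (0.0493) or M_1 (0.0270), or enhancer sgRNA M_1 (0.0303) or M_3 (0.0442), and Npy's without promoter sgRNA F_2 (0.0493) or Sim1 heterozygous F_3 (0.0366). With all libraries, Avp's also did in limma with age added (0.0479), only the compared groups (0.0236), stabilized values (0.0273), TMM scaling (0.0480) or the Gm42418 share (0.03825). It did with females only (0.00366) and in DESeq2 (0.0252) as well. It did not in edgeR, with a replicate block, without both B6 animals or without the 4 libraries that stood apart. Trh's did with age added (0.0374).

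The genes in this paragraph other than those named above were chosen after their values were seen. Spx, which encodes the peptide spexin, averaged 234 ± 154 normalized counts (SD, n = 4) in Sim1 heterozygous and 41.1 ± 11.4 (SD, n = 5) in wild-type hypothalamus, and every Sim1 heterozygous library, from 134 to 461, lay above every wild-type library. Gfap, an intermediate filament of astrocytes, averaged 28425 ± 8764 against 15157 ± 6665, and the complement genes C4b and C3 averaged 2906 ± 1202 against 1069 ± 354 and 367 ± 107 against 201 ± 24.0. Serpina3n, a protease inhibitor of reactive astrocytes, averaged 11353 ± 3287 against 6613 ± 1189. Slc6a3, the dopamine transporter, averaged 879 ± 317 against 380 ± 604, and wild type M_1 alone held 1459. In limma 0 genes passed an adjusted p of 0.05, and the smallest was 0.107 for Spx (log2 fold change 2.34, SE 0.376). In the same fit 768 genes, 415 higher and 353 lower, had an unadjusted p under 0.05, a count that ran from 490 without wild type M_1 to 2042 without Sim1 heterozygous F_1. edgeR called 0 genes and DESeq2 11 on the recovered reads, the latter Apoa1, C4b, Cep112it, Gm12945, Gm13405, Oxt, Serpina3k, Sprr1a, Spx, Timp1 and Tmem174. On simulated data of this comparison, with 100 genes changed 2-fold and 100 changed 4-fold, DESeq2 made 28 false calls, limma 6 and edgeR 5. Set beside the 83 and 99 changes it recovered, DESeq2's 28 false calls are a larger share than the 0.05 set. Those of limma (72 and 99 recovered) and edgeR (72 and 99) are a smaller share. DESeq2 thus did not hold its threshold in this simulation, and its calls in the real fits are uncertain to that extent. The counts themselves do not carry over to the real fits. Without enhancer sgRNA M_1 limma called 1 gene, Oxt, and without promoter sgRNA M_1 it called 1, Spx. The authors' table held 19 genes past their false discovery rate, 12 higher and 7 lower, among them C4b (1.24), Oxt (-3.21), Slc6a3 (3.23), Sim1 (-1.27), Spx (2.38), Gfap (0.80), Chrna6 (1.41), Avp (-1.13), Prlr (-0.81) and Trh (-0.71) on the log2 scale. Its values of 28.54 for Trim12a and 23.58 for Fabp1 lie outside the range of a measurable fold. C4b and Serpina3n have near-identical copies, Timp1 lies inside Syn1 on the other strand, and the strand used in counting is not stated, so their counts are uncertain.

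**Figure D2:**
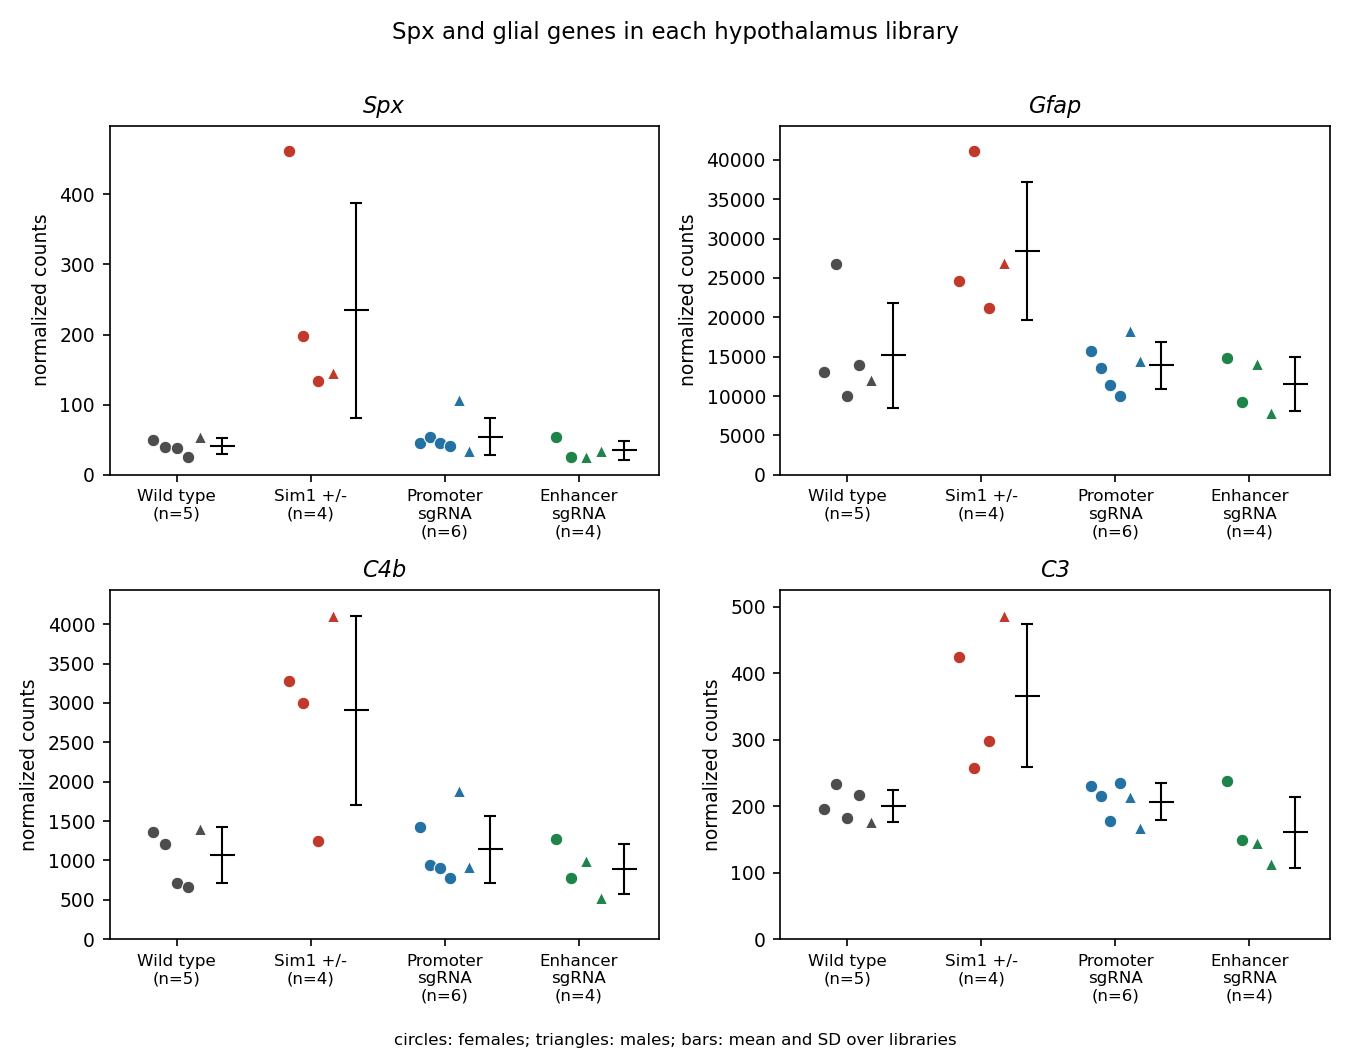
Normalized counts of Spx, Gfap, C4b and C3 in each hypothalamus library by group (circles females, triangles males, bars mean and SD). Spx lay between 134 and 461 in the 4 Sim1 heterozygous libraries and at most at 106 in the others.

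Among the cell types, all 13 microglial genes were higher in the Sim1 heterozygous group than in wild type, with a median log2 fold change of 0.28, and the complement genes C1qa (0.55), C1qb (0.51) and C1qc (0.49) led the list. Of 12 astrocyte genes 10 were higher, with Gfap ahead, and of 9 genes of oligodendrocyte precursors 7 were lower, with Vcan (-0.47) and Gpr17 (-0.36) ahead. Of 20 paraventricular neuroendocrine and SIM1 lineage genes 14 were lower, with Oxt and Avp ahead. Of 23 interferon response genes 18 were higher, among them Ifitm3 (0.79) and Ifit1 (0.79), and of 18 inflammatory genes 14 were higher. Camera with its preset correlation called 14 of the 29 lists, 9 up and 5 down. The adjusted p was 5.16e-08 for microglia (adjusted p = 0.322 with an estimated correlation), 0.0145 for astrocytes (0.576 with an estimated correlation), 0.00175 for oligodendrocyte precursors (0.322), 0.000498 for interferon genes (0.426), 0.0243 for inflammatory genes (0.324) and 0.0417 for paraventricular genes (0.455). Adjusted over the list alone, 4 microglial genes were higher, Gfap was the 1 astrocyte gene, Oxt was the 1 paraventricular gene, and no gene of the precursor, interferon or inflammatory lists passed. In the list of the suprachiasmatic nucleus, the circadian pacemaker, which camera did not call (adjusted p = 0.123), 1 gene was higher and 4 were lower when adjusted over the list alone, with Grp, Rorb, Syt10 and Avp ahead. Without Sim1 heterozygous M_1 the interferon call (0.0648) ended, and the inflammatory call ended without it, wild type F_3 or wild type M_1 (at most 0.132). The astrocyte call ended without Sim1 heterozygous F_3 or M_1, or wild type F_3 or M_1 (at most 0.970). The paraventricular call ended without promoter sgRNA F_2, Sim1 heterozygous F_3, or wild type F_1, F_2 or F_3 (at most 0.450).

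Markers of tissues around the hypothalamus and of blood differed between the same groups. Of 10 blood genes 9 were higher, with Hbb-bt (1.61) and Hba-a1 (1.38) ahead, and 3 passed when adjusted over the list alone. All 14 meningeal genes were higher (median log2 fold change 0.52), all 15 choroid plexus genes were lower (-1.01), all 15 thalamic genes were lower (-0.78) and 11 of 15 striatal genes were higher, with Tac1 (0.75) ahead and alone in passing when adjusted over the list alone. Camera's adjusted p was 2.99e-05 for blood (adjusted p = 0.322 with an estimated correlation), 1.15e-05 for choroid plexus (0.455 with an estimated correlation), 0.000112 for thalamus (0.455), 0.000180 for meninges (0.455) and 0.0296 for striatum (0.620). Housekeeping lists were called as well: 42 of 44 respiratory chain genes (adjusted p = 1.27e-09; 0.455 with an estimated correlation) and 55 of 64 ribosomal protein genes (9.34e-09; 0.455) were higher, and 15 of 16 clock genes were lower (0.00205; 0.426). Ribosomal genes averaged 1.28 above the mean of all libraries, on the log2 scale, in Sim1 heterozygous F_3, where neuronal genes averaged -0.60. Without Sim1 heterozygous F_3 the ribosomal (1.00), respiratory chain (0.0615) and clock (0.05002) calls ended. The meningeal call ended without Sim1 heterozygous F_4 or wild type M_1 (at most 0.106), and the striatal call without Sim1 heterozygous F_4, wild type F_2 or wild type F_4 (at most 1.00). The microglial, blood, choroid plexus, thalamic and precursor calls stayed under 0.05 without any 1 library. Leaving out 1 library does not test a mark carried by several. Choroid plexus genes averaged 3.25 and 1.455 above the mean of all libraries (log2) in wild type F_4 and F_3. The rest of wild type (-0.737 to -0.325) lay within the Sim1 heterozygous range (-0.826 to -0.219). Blood genes averaged 1.57 and 0.975 in Sim1 heterozygous F_3 and F_4, but also 1.14 in wild type F_2.

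**Figure D3:**
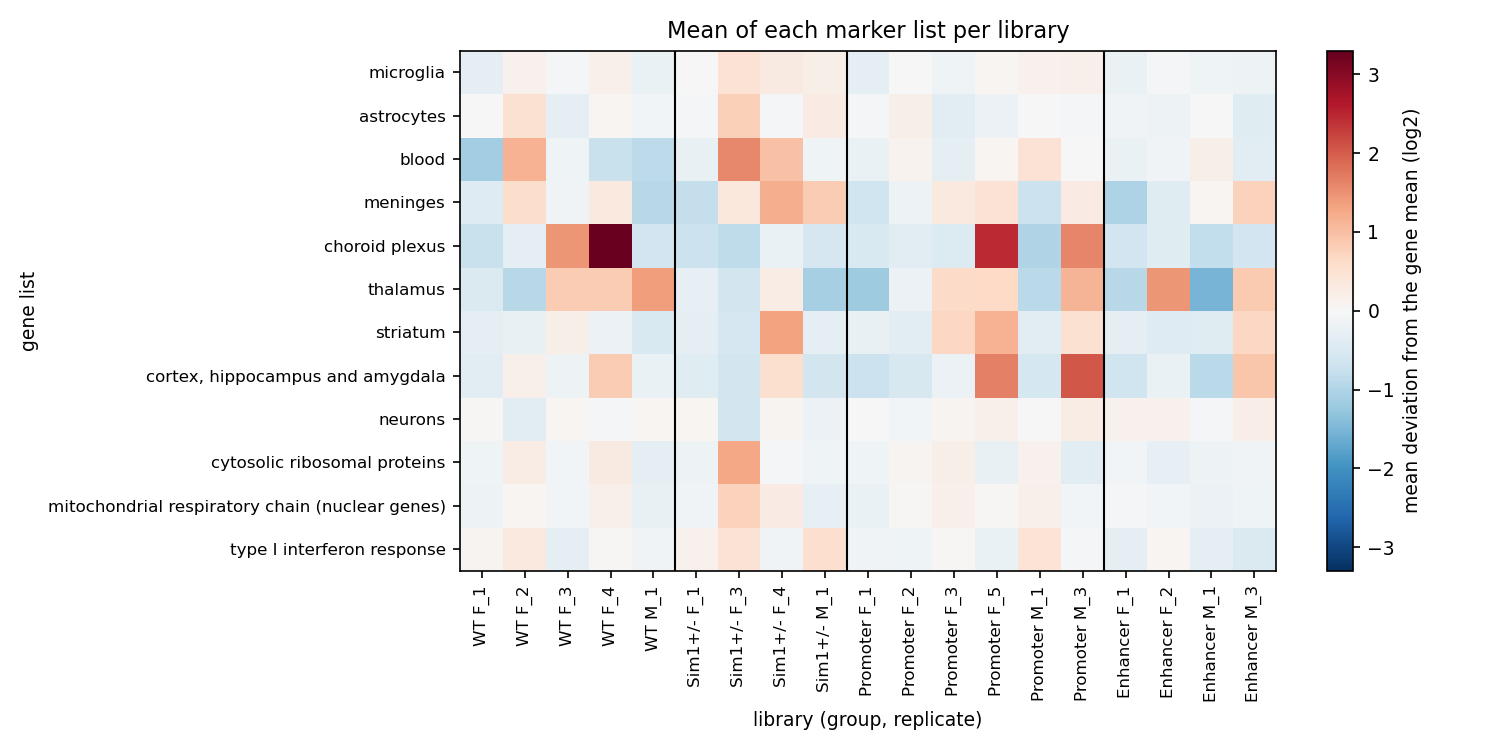
Mean deviation of 12 gene lists in each hypothalamus library from the mean of all libraries, on the log2 scale (columns libraries, boxes lists, colour the deviation). Choroid plexus genes stood highest in wild type F_4 (3.25) and ribosomal genes in Sim1 heterozygous F_3 (1.28).

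The comparison of promoter sgRNA with Sim1 heterozygous hypothalamus asks whether the guide at the Sim1 promoter raised Sim1 and what else differed. Sim1 averaged 117% of the Sim1 heterozygous mean, and the 6 promoter sgRNA libraries spread from 155 to 431 normalized counts. Oxt averaged 175% of the Sim1 heterozygous mean (1617 ± 758, SD, n = 6, against 924 ± 505, SD, n = 4). Avp averaged 5933 ± 1722 (SD, n = 6) against 5345 ± 1170 (SD, n = 4), Crh 251 ± 78.7 against 190.0 ± 97.5 and Trh 2883 ± 1072 against 2968 ± 470.0. In limma the log2 fold change of Sim1 was 0.23 (SE 0.287, adjusted p = 0.938) and that of Oxt 0.94 (SE 0.508, adjusted p = 0.934). The two-sided exact permutation p was 0.624 for Sim1 and 0.138 for Oxt over 210 splits. Adjusted over the list alone, no gene among Sim1 and the 14 passed, and the smallest p was 0.576. The other genes fixed for naming were at 0.15 for Avp (SE 0.253), 0.51 for Crh (SE 0.327), -0.10 for Trh (SE 0.248), -0.34 for Otp (SE 0.334), 0.00 for Arnt2 (SE 0.124), -0.55 for Sim2 (SE 0.292) and 0.11 for Pou3f2 (SE 0.128). Mc4r was at 0.15 (SE 0.216), Pomc at -0.55 (SE 0.511), Agrp at -0.76 (SE 0.514), Npy at -0.27 (SE 0.297), Lepr at -0.02 (SE 0.335) and Bdnf at 0.26 (SE 0.206). Without Sim1 heterozygous F_4 the log2 fold change of Sim1 was -0.01, and without Sim1 heterozygous F_1 it was 0.47.

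Spx averaged 54.1 ± 26.3 normalized counts (SD, n = 6) with the promoter sgRNA, where the Sim1 heterozygous group averaged 234 ± 154 (SD, n = 4). Gfap averaged 13898 ± 2979 (28425 ± 8764 in the Sim1 heterozygous group), C4b 1141 ± 427 (2906 ± 1202) and C3 207 ± 28.1 (367 ± 107), and these 4 genes were chosen after their values were seen. Limma called 0 genes, with the smallest adjusted p 0.456 for Spx (log2 fold change -2.01, SE 0.362), and 836 genes, 286 higher and 550 lower, had an unadjusted p under 0.05 (664 without promoter sgRNA F_5 to 1894 without Sim1 heterozygous F_1). edgeR called 0 genes and DESeq2 6 (C1s1, C4b, Cep112it, Gm13405, Slc43a3 and Spx) on the recovered reads. The authors' promoter comparison held 9 genes past their false discovery rate, all lower: C4b (-0.93), Bpifa1 (-29.26), Serpina3n (-0.57), Gm10800 (-12.88), Gfap (-0.74), Spx (-1.74), Cd74 (-1.14), Fgl2 (-0.91) and C3 (-0.79) on the log2 scale. Gm10800 stood at 34792 normalized counts in Sim1 heterozygous F_4 and at most at 165 in the other 18 libraries, and Bpifa1's value lies outside the range of a measurable fold. In that comparison Sim1 was at 0.47 with a false discovery rate of 1.00.

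All 13 microglial genes were lower with the promoter sgRNA than in the Sim1 heterozygous group (median log2 fold change -0.28), as were 19 of 23 interferon response genes (-0.33) and 11 of 12 astrocyte genes (-0.28). All 16 neuronal genes were higher (0.22), with the neurofilament genes Nefm, Nefh and Nefl ahead, and 12 of 20 paraventricular genes were higher (0.08). Camera called 15 of the 29 lists, 5 up and 10 down: its adjusted p was 1.30e-06 for microglia (adjusted p = 0.461 with an estimated correlation), 0.000208 for interferon genes, 0.000101 for astrocytes, 0.000101 for neurons and 0.0201 for inflammatory genes (0.461 with an estimated correlation for each), and it did not call the paraventricular list (0.413). Adjusted over the list alone, Gfap passed in the astrocyte list and no gene passed in the other 28 lists. Markers of neighbouring tissue moved too: 14 of 15 choroid plexus genes (0.68), 15 of 16 cortical genes (0.47) and all 15 thalamic genes (0.44) were higher, and 8 of 10 blood genes (-1.17), all 14 meningeal genes (-0.46), 13 of 14 ependymal genes (-0.27) and 12 of 15 endothelial genes (-0.11) were lower. Their adjusted p ran from 0.000132 for meninges to 0.0466 for endothelium, and from 0.461 to 0.619 with an estimated correlation. Ribosomal (59 of 64, 5.20e-07) and respiratory chain genes (38 of 44, 0.00536) were lower and clock genes (16 of 16, 0.00126) higher, with 0.557, 0.685 and 0.461 with an estimated correlation. Without Sim1 heterozygous F_3 the ribosomal (1.00), neuronal (0.173), astrocyte (0.177), clock (0.0549) and blood (0.0549) calls ended, and without Sim1 heterozygous F_4 the meningeal call did (0.105). The inflammatory call ended without Sim1 heterozygous M_1 or promoter sgRNA F_1 or M_1, the cortical call without Sim1 heterozygous M_1 or promoter sgRNA F_5 or M_3, and the thalamic call without Sim1 heterozygous M_1 or promoter sgRNA F_3 or M_3. The respiratory chain call ended without Sim1 heterozygous F_3 or F_4 or promoter sgRNA F_1, the ependymal call without Sim1 heterozygous F_3 or M_1 or promoter sgRNA F_3, and the endothelial call without Sim1 heterozygous F_3, F_4 or M_1 or promoter sgRNA F_1, F_3 or M_1. Choroid plexus Ttr stood at 35774 and 18742 normalized counts in promoter sgRNA F_5 and M_3.

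The comparison of enhancer sgRNA with Sim1 heterozygous hypothalamus asks the same of the guide at the enhancer. Sim1 averaged 142% of the Sim1 heterozygous mean, and 3 of the 4 Sim1 heterozygous libraries lay below all enhancer sgRNA libraries. Oxt averaged 217% of the Sim1 heterozygous mean (2006 ± 1649, SD, n = 4, against 924 ± 505, SD, n = 4), a difference smaller than the spread of the enhancer sgRNA group. Avp averaged 4526 ± 1539 (SD, n = 4) against 5345 ± 1170 (SD, n = 4), and Trh 3109 ± 930 against 2968 ± 470.0. In limma the log2 fold change of Sim1 was 0.61 (SE 0.318, adjusted p = 0.678) and that of Oxt 0.86 (SE 0.564, adjusted p = 0.687). The two-sided exact permutation p was 0.171 for Sim1 and 0.286 for Oxt over 70 splits. Adjusted over the list alone, all 15 p-values were 0.979 in limma. With the authors' stabilized values, a setting chosen after the data were seen, Sim1 (log2 fold change 0.41) and Oxt (1.32) passed in limma, with 0.0244 and 0.0144 adjusted over the list alone. The other genes fixed for naming were at -0.23 for Avp (SE 0.281), 0.10 for Crh (SE 0.363), 0.07 for Trh (SE 0.275), 0.01 for Otp (SE 0.371), 0.07 for Arnt2 (SE 0.138), -0.05 for Sim2 (SE 0.324) and -0.02 for Pou3f2 (SE 0.142). Mc4r was at -0.14 (SE 0.240), Pomc at -0.39 (SE 0.568), Agrp at -0.67 (SE 0.570), Npy at -0.30 (SE 0.3295), Lepr at 0.01 (SE 0.372) and Bdnf at 0.16 (SE 0.229). Without Sim1 heterozygous F_1 the log2 fold change of Sim1 was 0.84, past 0.05 in limma before adjustment, and without Sim1 heterozygous F_4 it was 0.38. Without enhancer sgRNA F_2 that of Oxt was 0.36, and without enhancer sgRNA M_1 it was 1.54, the latter with a p of 0.0190 in limma adjusted over the list alone.

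Spx averaged 34.6 ± 13.4 normalized counts (SD, n = 4) with the enhancer sgRNA, where the Sim1 heterozygous group averaged 234 ± 154 (SD, n = 4). Gfap averaged 11478 ± 3437, C4b 894 ± 319 and C3 161 ± 53.5 with the enhancer sgRNA, each below the Sim1 heterozygous means given above, and these 4 genes were chosen after their values were seen. Limma called 0 genes, with the smallest adjusted p 0.0622 for Spx (log2 fold change -2.61, SE 0.403), and 1368 genes, 594 higher and 774 lower, had an unadjusted p under 0.05 (691 without Sim1 heterozygous F_3 to 2846 without Sim1 heterozygous F_1). Without promoter sgRNA M_1 limma called 1 gene, Spx, and without enhancer sgRNA F_1 it called 3, C3, Guca1a and Spx. edgeR called 0 genes and DESeq2 15 on the recovered reads, 2 higher and 13 lower, among them C3, C4b, Cebpd, Cep112it, Clec3b, Gfap, Gm13405, Guca1a, Perp, Sprr1a, Spx, Timp1, Tspo and Tubb6. The authors' enhancer comparison held 7 genes past their false discovery rate, 3 higher and 4 lower: Gfap (-1.40), C4b (-1.34), Ackr1 (1.15), Oxt (3.07), Olfml3 (-1.05), Zfp133-ps (3.89) and C3 (-1.36) on the log2 scale. In that comparison Sim1 was at 1.25 with a false discovery rate of 0.0511. Which samples that table set against each sgRNA is not stated in it. Cebpd, Timp1, Ackr1 and Zfp133-ps overlap other annotated genes, so their counts are uncertain.

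All 13 microglial genes were lower with the enhancer sgRNA than in the Sim1 heterozygous group (median log2 fold change -0.43), among them C1qa (-0.51) and Siglech (-0.58), and 10 passed when adjusted over the list alone. Of 23 interferon response genes 20 were lower (-0.50), among them Ifitm3 (-0.97), Rtp4 (-0.82) and Ifit1 (-0.96), and 7 passed when adjusted over the list alone. All 12 astrocyte genes were lower (-0.31), with Gfap the 1 that passed when adjusted over the list alone, and 16 of 18 inflammatory genes were lower (-0.28). Of 9 genes of oligodendrocyte precursors 6 were higher (0.32), and 4 passed when adjusted over the list alone, with Gpr17 (0.43), Cspg4 (0.57) and Vcan (0.50) ahead. All 16 neuronal genes were higher (0.27), and 13 of 20 paraventricular genes (0.07). Camera called 14 of the 29 lists, 4 up and 10 down: its adjusted p was 6.31e-09 for microglia, 7.17e-07 for interferon genes, 0.00343 for precursors and 0.00468 for inflammatory genes (adjusted p = 0.198 with an estimated correlation for each), and 1.45e-05 for astrocytes and 0.000104 for neurons (0.394 with an estimated correlation). It did not call the paraventricular list (0.421). Neighbouring tissue and housekeeping lists were called as well, with 12 of 14 ependymal genes lower (-0.48, Vim ahead at -0.54 and alone in passing when adjusted over the list alone), all 14 meningeal genes lower (-0.59), 9 of 10 blood genes lower (-1.02), 14 of 15 thalamic genes higher (0.45), 59 of 64 ribosomal and 38 of 44 respiratory chain genes lower, 10 of 16 glucocorticoid-induced genes lower and 13 of 16 clock genes higher. Their adjusted p lay between 6.92e-10 and 0.0411, and between 0.394 and 0.762 with an estimated correlation. Calls ended without Sim1 heterozygous M_1 for inflammatory genes (0.0507), without Sim1 heterozygous F_4 for blood (0.0568) and without Sim1 heterozygous F_4 or enhancer sgRNA F_1 for meninges (at most 0.0698). The thalamic call ended without Sim1 heterozygous M_1 or enhancer sgRNA F_2 or M_3, the clock call without Sim1 heterozygous F_3 or M_1, promoter sgRNA M_1 or enhancer sgRNA F_2 or M_3, and the glucocorticoid call without Sim1 heterozygous F_1 or F_4 or enhancer sgRNA F_1 or F_2.

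Enhancer sgRNA was set directly against promoter sgRNA to ask whether the guides differ in effect. Sim1 averaged 122% of the promoter sgRNA mean with the enhancer sgRNA, a log2 fold change of 0.38 (SE 0.289, limma adjusted p = 0.9989, exact permutation p = 0.376 over 210 splits). Of 16 glucocorticoid-induced genes 15 were lower with the enhancer sgRNA (median log2 fold change -0.19), with Sgk1, Tsc22d3, Ddit4 and Pdk4 ahead and none passing when adjusted over the list alone. Camera called 11 of the 29 lists, 1 up and 10 down, among them glucocorticoid-induced genes (adjusted p = 0.000382; 0.292 with an estimated correlation), heat shock genes (0.000460; 0.765), immediate early genes (0.00414; 0.765), choroid plexus genes (0.000785; 0.765) and cortical genes (0.00414; 0.765). The other called lists were respiratory chain, interferon, ribosomal, microglial and ependymal genes, lower, and oligodendrocyte precursors, higher, with an adjusted p of at most 0.0214, and of at least 0.670 with an estimated correlation. The glucocorticoid call alone stayed under 0.05 without any 1 library (at most 0.00438). Without promoter sgRNA M_1 the heat shock, respiratory chain, interferon, ribosomal, microglial, ependymal and precursor calls ended. The choroid plexus and cortical calls ended without promoter sgRNA F_5 or M_3, the cortical call also without enhancer sgRNA M_1, and the immediate early call without promoter sgRNA F_5 or enhancer sgRNA F_1. Other omissions that ended calls were enhancer sgRNA M_3 for interferon, microglial, ependymal and precursor genes, enhancer sgRNA F_2 for ribosomal and ependymal genes, promoter sgRNA M_3 for microglial genes and promoter sgRNA F_1 for precursors. In promoter sgRNA F_5 immediate early genes averaged 1.30 and cortical genes 1.67 above the mean of all libraries on the log2 scale. Limma called 0 genes, with 501 at an unadjusted p under 0.05 (223 higher, 278 lower; 354 without enhancer sgRNA F_1 to 753 without promoter sgRNA F_1), and edgeR and DESeq2 called 0 genes. Without promoter sgRNA F_1 the log2 fold change of Sim1 was 0.55, with an unadjusted limma p of 0.0498.

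The comparisons of each sgRNA with the Sim1 heterozygous group share those 4 control libraries, which alone gives a resemblance. Over genes, the log2 fold changes of both comparisons correlated at r = 0.653, and simulated unchanged groups against the shared controls gave 0.549 over 100 simulations. The covariance was 0.114 and the simulated one 0.0821, a difference of 0.0319. At an unadjusted p under 0.05, 74 genes were higher in both (127 simulated, 8.29 for independent lists), 232 were lower in both (125 simulated, 20.8 for independent lists) and 0 went in opposite directions. With the controls divided between the comparisons, 2 libraries each, r had a median of -0.0452 over 6 such divisions, from -0.0925 to 0.0464, and the median covariance was -0.0135. Genes are not independent replicates in these values.

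Both sgRNA groups were also set against wild type, to ask how far each stood from animals with 2 copies of Sim1. With the promoter sgRNA Sim1 stood at 58.3% of wild type and Oxt at 24.1% (1617 ± 758, SD, n = 6, against 6698 ± 2357, SD, n = 5). Avp stood at 64.9% of wild type there, and 42 of 44 respiratory chain genes and 13 of 15 striatal genes were higher, with Tac1 (0.42) ahead. With the enhancer sgRNA Sim1 stood at 71.0% of wild type, Oxt at 29.9% and Avp at 49.5%, and all 15 choroid plexus genes were lower (median log2 fold change -0.91). In limma the log2 fold change against wild type was -0.85 for Sim1 (SE 0.270, adjusted p = 0.0406), -1.95 for Oxt (SE 0.478, adjusted p = 0.00930), -0.57 for Avp (SE 0.239, 0.0982) and -0.59 for Trh (SE 0.233, 0.0982) with the promoter sgRNA. These values are adjusted over the list alone. It was -0.46 for Sim1 (SE 0.305, 0.434), -2.03 for Oxt (SE 0.540, 0.0160) and -0.95 for Avp (SE 0.269, 0.0160) with the enhancer sgRNA. With the enhancer sgRNA, the Oxt call ended without enhancer sgRNA F_1 (0.0567) and the Avp call without enhancer sgRNA F_2 (0.0668) or M_1 (0.0759). The Avp call also ended in limma without both B6 animals (0.0522), and both calls ended with only the compared groups (0.0601 each) and in edgeR (0.0562 for Oxt and 0.0512 for Avp). With the promoter sgRNA, the Sim1 call ended in limma without any 1 of promoter sgRNA F_2, F_3, F_5 or M_3, wild type F_1, F_2 or F_3, enhancer sgRNA F_1 or Sim1 heterozygous M_1 (adjusted p at most 0.133). It also ended with females only (0.0775), without both B6 animals (0.118), without trend (0.0745), without the 4 libraries that stood apart (0.306) and in edgeR (0.0863), while the Oxt call stayed in every setting. With the promoter sgRNA, Avp passed without promoter sgRNA M_1 (0.0116) or wild type M_1 (0.0384), and Trh without promoter sgRNA M_1 (0.00992) or wild type F_4 (0.0218). The exact permutation p, two-sided, was 0.0260 for Sim1, 0.00216 for Oxt and 0.0476 for Avp with the promoter sgRNA over 462 splits (0.195, 0.0325 and 0.238 adjusted over those genes). With the enhancer sgRNA it was 0.0397 for Sim1, 0.0238 for Oxt, 0.0317 for Avp and 0.0159 for Npy over 126 splits (0.149 adjusted for each). Npy stood at 137% of wild type there.

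Camera called 5 lists in each comparison with wild type. With the promoter sgRNA all 5 were higher: respiratory chain (1.43e-05), striatum (1.43e-05), heat shock genes (0.0111), neurons (0.0333) and glucocorticoid-induced genes (0.0348), with an adjusted p of 0.815 or more with an estimated correlation. With the enhancer sgRNA, choroid plexus (1.18e-06), ependymal (0.000157), astrocyte (0.00203) and interferon genes (0.00320) were lower and neurons (0.00179) higher, with an adjusted p of 0.779 or more with an estimated correlation. Of these, respiratory chain and striatum with the promoter sgRNA and choroid plexus with the enhancer sgRNA stayed under 0.05 without any 1 library. The heat shock call ended without promoter sgRNA F_1 or M_1 or wild type F_2 or M_1, the glucocorticoid call without promoter sgRNA F_1, F_3 or F_5 or wild type F_1 or F_2, and the neuronal call without promoter sgRNA F_1, F_3, F_5 or M_3 or wild type F_2. With the enhancer sgRNA, interferon and ependymal calls ended without enhancer sgRNA M_3, the neuronal call without wild type F_2 and the astrocyte call without either. Ttr, the most abundant choroid plexus transcript, stood at 73295 and 11036 normalized counts in wild type F_4 and F_3. The choroid plexus list averaged 3.25 and 1.455 above the mean of all libraries (log2) there. It averaged -0.737 to -0.325 in the rest of wild type and -0.8195 to -0.408 in the enhancer sgRNA libraries. Leaving out 1 library does not remove both high ones. Limma called 0 genes in both comparisons, with 433 (191 higher, 242 lower) at an unadjusted p under 0.05 for the promoter sgRNA and 259 (87 higher, 172 lower) for the enhancer sgRNA, the latter 183 without wild type F_4 and 465 without wild type M_1. edgeR called 0 genes in both, and DESeq2 called 2 in each, Gm12945 and Tmem174. Adjusted over the list alone, Oxt passed in the paraventricular list with the promoter sgRNA, and Oxt and Avp with the enhancer sgRNA.

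Of the genes within 1 Mb of Sim1, Ascc3 and Lilrb4a were expressed enough to be tested, and 0 passed in any of the 6 comparisons, in limma at an adjusted or at an unadjusted p of 0.05. Ascc3 was at -0.32 in Sim1 heterozygous against wild type, and at 0.34 and 0.38 with the promoter and enhancer sgRNA against Sim1 heterozygous, on the log2 scale. Lilrb4a was at 1.24, -1.23 and -0.67 in the same comparisons.

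The ChIP peak lists ask where Cas9 bound on and off target. Each list stands for 1 sgRNA and 1 antibody, for which the labels give 2 replicates, so a list has no replicate error. In hypothalamus the labels give females for the promoter sgRNA and males pooled with females for the enhancer sgRNA, so sex differs between these lists. With the S. pyogenes Cas9 (SpCas9) antibody, hypothalamus held 92 peaks for the promoter sgRNA and 137 for the enhancer sgRNA, with median fold enrichments of 12.5 and 8.60. With the S. aureus Cas9 (SaCas9) antibody it held 140 and 121 peaks, with medians of 4.61 and 2.95, and Neuro2A cells held 127 and 205 peaks with the SpCas9 antibody, with medians of 3.60 and 9.52. Within 1 Mb of Sim1 every list held 2 peaks. In the promoter sgRNA list of SpCas9 in hypothalamus, 1 lay at 50893924 to 50894717 on chromosome 10 (GRCm38), 37 bp upstream of Sim1, and the other at 51257361 to 51258161, in intergenic sequence 268209 bp past the end of Sim1 and 222451 bp from Lilrb4a. The promoter peak's fold enrichment was 174.5 and the distal peak's 180.1 with the promoter sgRNA, and 134 and 143 with the enhancer sgRNA, for SpCas9 in hypothalamus. With the SaCas9 antibody the promoter and distal peaks had folds of 67.3 and 69.7 for the promoter sgRNA and of 38.0 and 39.0 for the enhancer sgRNA. In Neuro2A cells they had folds of 58.1 and 43.2 for the promoter sgRNA and of 119 and 130.4 for the enhancer sgRNA. The fold of the site named by the sgRNA over that of the other site lay between 0.965 and 1.35 over the 6 lists, so both sites were enriched whichever guide the label gives. Both were the peaks of highest fold in the SaCas9 and Neuro2A lists. All fold enrichments and scores are the authors', and the control behind them is not given in the sources used here.

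**Figure D4:**
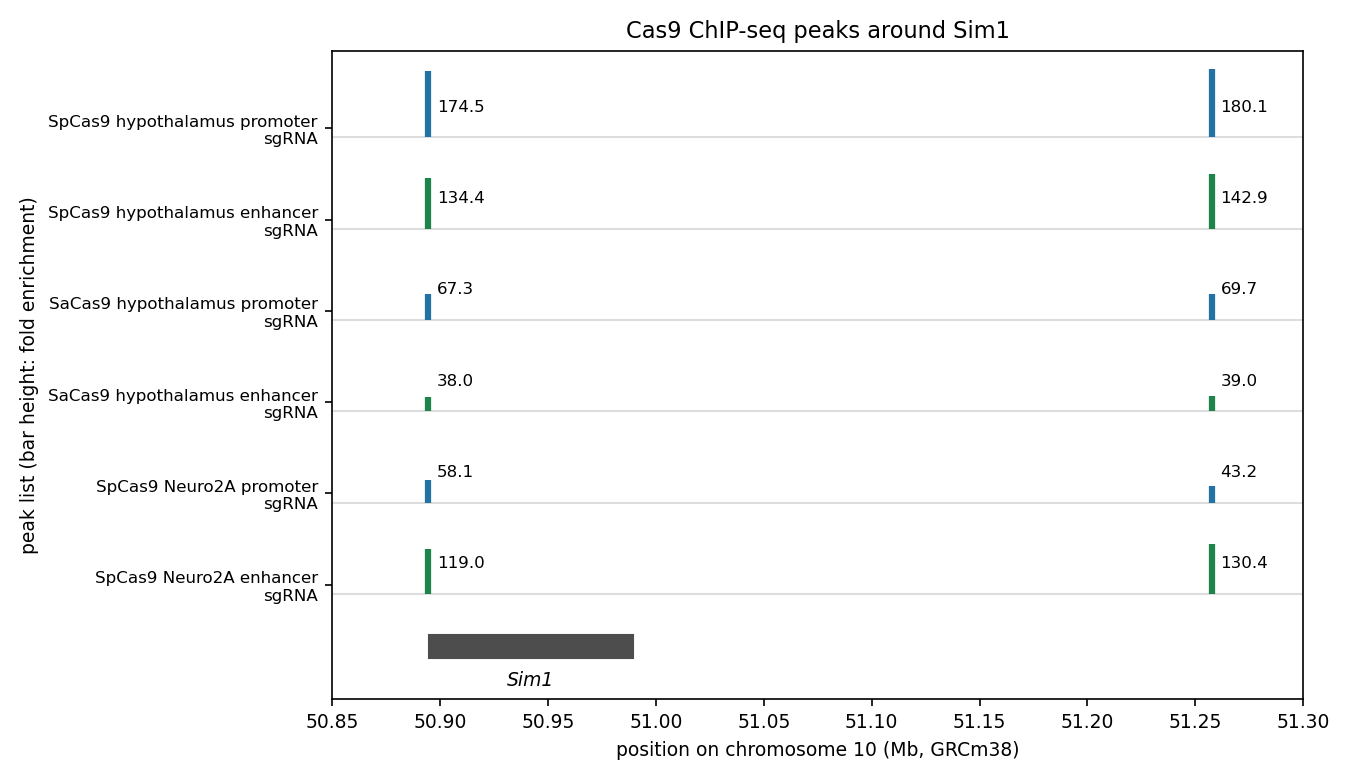
Peaks of the 6 lists on chromosome 10 around Sim1 (horizontal axis position in Mb, GRCm38, bar height the authors' fold enrichment, blue promoter sgRNA lists, green enhancer sgRNA lists). Every list held 1 peak at the Sim1 promoter and 1 peak 268 kb past the gene's end.

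Away from Sim1, the SpCas9 lists of hypothalamus shared their strongest sites. The peak of highest score lay on chromosome 14 at 15657551 to 15658482, 205106 bp from B230110C06Rik, with folds of 266 and 200.2 for the promoter and enhancer sgRNA. Prkag2, a regulatory subunit of AMP-activated kinase, lay 1199 bp from a peak on chromosome 5 at 24860753 to 24861545 with a fold of 174.6, and 1212 bp from it in the enhancer sgRNA list, where the fold was 99.4. A peak on chromosome 2 at 148839384 to 148840082, 6629 bp from 9230104L09Rik, had folds of 117 and 91.9. Of the 92 promoter sgRNA peaks 70 (76.1%) overlapped an enhancer sgRNA peak, and 69 of 137 did the reverse. In the SaCas9 lists and the Neuro2A list of the promoter sgRNA the other high-scoring peaks were a region inside Gm10801 on chromosome 2 (98662033 to 98663161, fold 8.07 in the promoter sgRNA list, 4.74 and 6.86 in the others) and 2 stretches of the mitochondrial genome. The Neuro2A list of the enhancer sgRNA held peaks on chromosome 15 at 74481220 to 74482153 (fold 86.5, 34042 bp from Adgrb1), on chromosome 1 at 32972826 to 32973536 (fold 94.6, 127371 bp from Gm7114) and in Gm10801 (fold 20.2). Of the 140 SaCas9 promoter sgRNA peaks 100 overlapped a promoter sgRNA peak of Neuro2A cells, and of the 92 SpCas9 promoter sgRNA peaks of hypothalamus 33 overlapped a SaCas9 one. Unplaced scaffolds carried 35 and 37 of the SaCas9 peaks and 41 and 46 of the Neuro2A peaks, and the first 3.1 Mb of chromosome 9 between 19 and 21 in each of these lists. Peaks there, in Gm10801 and on mitochondrial DNA recurred with either guide and antibody, in hypothalamus and in Neuro2A cells. They are therefore not shown to be Cas9 binding, and background signal was not tested. The overlaps between lists count these peaks too. The 6 lists merged into 356 sites, of which 164 occurred in 1 list and 11 in all 6. Of those 11 sites 2, the pair at Sim1, had a fold of at least 20 in every list.

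No excess of genes with a low p near the peaks passed the test. Prkag2 was at -0.08 with the promoter sgRNA and at -0.19 with the enhancer sgRNA against Sim1 heterozygous, on the log2 scale, and passed no adjusted threshold. With the enhancer sgRNA its unadjusted limma p was under 0.05, so it is among the genes counted below at that threshold. Of the genes within 100 kb of a peak, 0 passed limma's adjusted p of 0.05 for any of the 6 lists, and edgeR called 0 genes in any comparison. None of the 6 and 15 genes called by DESeq2 lay there. Of the authors' calls, Gm10800 lay near a peak of each promoter sgRNA list, and a Neuro2A enhancer sgRNA peak (fold 12.2) lay inside Olfml3, which was at -0.56 in limma (adjusted p = 0.678). The share with an unadjusted p under 0.05 was highest near the enhancer sgRNA peaks of SpCas9 in hypothalamus, at 36 of 402 genes (8.96%, with 6.63% elsewhere). Fisher's exact test, two-sided, gave p = 0.0688 for it, and 0.413 after adjustment over the 6 lists, the lowest of them. The counts for the other lists were 11 of 318 genes (promoter sgRNA, SpCas9, hypothalamus), 12 of 238 and 7 of 147 (SaCas9 promoter and enhancer sgRNA), and 6 of 162 and 32 of 411 (Neuro2A promoter and enhancer sgRNA).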

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

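The tests on glial genes, on Slc6a3 and on the peaks at Sim1, and the counts of splits for genes at an unadjusted p under 0.05, were chosen only after their results were seen, and the counts of splits for gene lists were planned.

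Genes of reactive glia were higher in the Sim1 heterozygous group: over a list of 24, 7 of which prompted it (Gfap, Serpina3n, C4b, C3, Osmr, Timp1 and Cebpd), each of the 4 Sim1 heterozygous libraries (0.372 to 0.916 above the mean of all libraries, log2) lay above all 15 others (at most 0.312). Over the other 17 members, Sim1 heterozygous and enhancer sgRNA libraries did not separate fully (two-sided exact permutation p = 0.0857 over 70 splits, 0.0286 over all 24). The difference of the list mean from wild type was 0.786 (SE 0.178). The share of reads on Gm42418 (0.7849 with it as covariate, SE 0.185) and liver RNA in Sim1 heterozygous F_4 (0.866 without that library, SE 0.194) are both argued against, since the difference stayed over 4 SE above 0, and over 3 SE for the other 17 members alone (0.655, SE 0.203, and 0.716, SE 0.218). A larger share of astrocytes is argued against by the other 17 members, which exceeded the astrocyte list by 0.5172 (SE 0.213), while the astrocyte list, here without the genes it shares with the reactive list (Gfap among them), differed by 0.142 (SE 0.184). More meninges or blood in the tissue, whose lists were also higher, are argued against as the whole of it: with the meningeal mean as covariate the difference was 0.8332 (SE 0.187; 0.675, SE 0.211, for the 17), and with the blood mean 0.7097 (SE 0.205; 0.568, SE 0.2245). Over those 17 members the lowest Sim1 heterozygous library stood 0.2289 above the highest wild-type one (exact permutation p = 0.00794, 0.0286 adjusted over 6 comparisons). This separation restates the difference between the groups and does not test its cause. With age as covariate the difference was 0.663 (SE 0.186). The promoter and enhancer sgRNA animals were also Sim1 heterozygous, yet averaged -0.155 and -0.116 over the 17 members, near wild type at -0.141. A state of glia from the loss of 1 Sim1 copy alone would be met in them too, unless the guides reversed it, which was not tested. Litter, housing and body weight are not given in the sources used here and stay open, as does a change in microglia, whose list was also higher.

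Slc6a3, the dopamine transporter, stood between 526.8 and 1280 normalized counts in the Sim1 heterozygous libraries and between 83.1 and 134.9 in 4 wild-type libraries, all female, but at 1459 in wild type M_1 and at 2376.8 in promoter sgRNA F_2 (358.2 to 1087 in the other 5 of that group), and both of these lay apart from their group. With the enhancer sgRNA it stood between 398.4 and 1242. Every library with 1 working Sim1 copy, with or without a guide, thus lay above all wild-type females, though not above wild type M_1. More midbrain tissue in some dissections may account for some of the spread in Slc6a3: within groups Slc6a3 followed the other midbrain dopamine markers over 19 libraries (r = 0.7246, permutation p = 0.00029; Spearman's rho 0.653, p = 0.0032). Without wild type M_1 and promoter sgRNA F_2 r was 0.522 (permutation p = 0.031), and within groups and age classes it was 0.664 over 18 libraries (permutation p = 0.0171). A relation within groups does not test the difference between groups. The mean of the dopamine list, which holds Slc6a3, was -0.306 in Sim1 heterozygous F_4 and -0.292 in wild type F_1, where Slc6a3 stood at 526.8 and 134.9. In the other Sim1 heterozygous libraries that mean (0.024 to 0.718) lay above all wild-type females. The relation does not exclude an added change within dopamine neurons, which was not tested.

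Both sites at Sim1 were peaks in all 6 lists, whichever guide and antibody the labels give. Reads of the SpCas9 hypothalamus libraries mixed into the SaCas9 libraries could put them there, and of 10 other high SpCas9 peaks at most 2 were found in a SaCas9 list. The highest SpCas9 peak, on chromosome 14 (pileups 378 and 376), had a fold of 6.62 in the SaCas9 enhancer sgRNA list and was absent from the SaCas9 promoter sgRNA list. These values go against mixing in that direction but do not exclude it, since the 12 pileups at the Sim1 sites were nearly equal (192 to 268, mean 246) while folds spread 4.73 times. Their SD of 21.0 is close to the 15.7 of counting alone, so pileups at such sites may be saturated and not follow the number of reads. Against this, other sequence had higher pileups, up to 427 on placed chromosomes and up to 551 on mitochondrial DNA, so saturation is not shown either. In the reverse direction, 9 and 8 of 10 other high SaCas9 enhancer sgRNA peaks were found in the SpCas9 promoter and enhancer sgRNA lists of hypothalamus. Of 10 SaCas9 promoter sgRNA peaks, 2 and 2 were found there. Mixing of SaCas9 reads into those libraries stays open, since sites shared for other reasons would be found too. Mixing between the SpCas9 hypothalamus libraries also stays open (all 10 of 10 were found, which a shared binding pattern would give too), as does contact between promoter and distal site in the nucleus, for which the named site's fold was at most 1.346 times the other's. Presence of both guides in 1 sample, and lists that join samples, were not tested, and the lists alone cannot separate these from biology.

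Other libraries lay far from the rest of their group, which chance gives in about 1 of 20 groups: 6 of 84 groups tested did, where 4.2 were to be met by chance. Oxt stood at 3111.8 normalized counts in promoter sgRNA F_5 (1052.6 to 1565 in the other 5). Lepr stood at 161.5 in wild type F_4 (80.3 to 101.6 in the other 4). Spx stood at 106.3 in promoter sgRNA M_1 (33.9 to 53.4 in the other 5). Gfap stood at 26795.6 in wild type F_2 (10040.4 to 13933.4 in the other 4).

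Other splits of the same libraries into groups of the same sizes gave results as large in every comparison, so chance cannot be excluded for any of these counts. The numbers of splits given here include the real grouping itself. For genes at an unadjusted p under 0.05, 48 of 100 splits reached the 768 genes of Sim1 heterozygous against wild type (highest other 4901), 71 of 100 the 836 of promoter sgRNA against Sim1 heterozygous (5036) and 11 of 35 the 1368 of enhancer sgRNA against Sim1 heterozygous (2892). For enhancer against promoter sgRNA, 77 of 100 reached 501 (2470), and against wild type 72 of 100 reached the 433 of the promoter sgRNA (2356) and 66 of 100 the 259 of the enhancer sgRNA (1295). For lists called by camera, 15 of 100 splits reached 14 (highest other 17), 9 of 100 reached 15 (19), 4 of 35 reached 14 (16), 41 of 100 reached 11 (18), 91 of 100 reached 5 (20) and 97 of 100 reached 5 (16), in the same order of comparisons. Splits that call several times the real number of genes point to a structure of the samples other than the groups. The highest other split divided animals of up to 4 months unevenly. In the same order they were 3 of 4 against 1 of 5, 2 of 6 against 3 of 4 and, less unevenly, 1 of 4 against 2 of 4. Then came 3 of 4 against 1 of 6, 1 of 6 against 4 of 5 and 0 of 4 against 3 of 5. Age class is thus a candidate for this structure, which was not tested.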

How the results depend on the processing

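Fits on the recovered reads (edgeR and DESeq2), stabilized values, TMM scaling, the Gm42418 share and the fit without 4 libraries were chosen after the data were seen. Limma without trend, a pseudocount of 0.1, no filter, no sex term, females only, without the B6 animals, edgeR, TMM and the fit without 4 libraries left the counts of genes at 0, except where given here. The size factors planned against TMM were not run, since the deposited values carry 1 scaling already. Apart from values left out below, 263 results of other settings stayed on their side of the threshold, as did 1309 values of named genes, while 27 further values gained and 8 lost a call, all in the same direction. The cause of the changes was not tested.

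Genes past an adjusted p of 0.05 (0 in limma in all comparisons) numbered, in Sim1 heterozygous against wild type, 1 with age added (Spx), 1 with only the compared groups (Oxt), 4 with a replicate block, 11 with DESeq2, 25 with DESeq2 and the block, 6 with stabilized values and 1 with the Gm42418 share. They numbered 6 with DESeq2 and 17 with DESeq2 and the block for promoter sgRNA against Sim1 heterozygous. For enhancer sgRNA against Sim1 heterozygous they numbered 1 without sex, 3 with age, 4 with the replicate block, 15 with DESeq2, 27 with DESeq2 and the block and 1 with the Gm42418 share. For enhancer against promoter sgRNA they numbered 18 with DESeq2 and the block. Against wild type they numbered 2 and 8 with DESeq2 without and with the block and 1 with stabilized values for the promoter sgRNA, and 2 and 10 with DESeq2 without and with the block for the enhancer sgRNA. Genes at an unadjusted p under 0.05 moved by over 1.5 times, in that order, to 1922 (stabilized values) and 1217 (without the 4 libraries), to 457 (only the compared groups) and 541 (without the 4 libraries), and to 734 (only the compared groups), 724 (without the B6 animals), 688 (stabilized values) and 520 (Gm42418 share). For enhancer against promoter sgRNA they moved to 811 (age), 944 (only the compared groups), 850 (without the B6 animals), 252 (females only) and 327 (stabilized values). Against wild type they moved to 1255 (stabilized values) and 656 (Gm42418 share) for the promoter sgRNA, and for the enhancer sgRNA to 395 (age), 393 (only the compared groups), 620 (replicate block), 602 (DESeq2 with the block) and 96 (stabilized values).

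Sim1's log2 fold change passed an unadjusted p of 0.05 for enhancer sgRNA against Sim1 heterozygous with age added (0.71) and with stabilized values (0.41), and for enhancer against promoter sgRNA with stabilized values (0.24). For enhancer sgRNA against wild type it passed with only the compared groups (-0.42), the replicate block (-0.66), DESeq2 with the block (-0.63) and the Gm42418 share (-0.64). Adjusted over Sim1 and the 14 genes, its calls against wild type were lost in settings given in the report. It gained a call for enhancer sgRNA against Sim1 heterozygous with stabilized values (0.0244), and against wild type with the replicate block (0.0393) and with DESeq2 and the block (0.0330).

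Lists called by camera fell to 0 in all 6 comparisons with an estimated correlation and with fry by direction. Among its mixed tests fry called 1 (interferon genes with the enhancer sgRNA against Sim1 heterozygous). With the replicate block they numbered 15, 11, 12, 4, 8 and 11 in the order of comparisons in the report (Sim1 heterozygous against wild type, promoter and enhancer sgRNA against Sim1 heterozygous, enhancer against promoter sgRNA, promoter and enhancer sgRNA against wild type). Without the 4 libraries they numbered 12 for promoter and 8 for enhancer sgRNA against wild type. The labels do not say that the numbers in the titles pair the animals. Same-numbered libraries deviated together at over 0.1 in 11 of 20 pairs but not in all (-0.140 to 0.231). That 12 of 19 libraries correlated best with their own number is a hint from the data, not the design, and animals of a number were mostly of similar age.

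With 1 library left out in turn, the counts of genes ran from 0 to 1 (Sim1 heterozygous against wild type) and 0 to 3 (enhancer sgRNA against Sim1 heterozygous). Sim1's log2 fold change ran from -1.33 to -0.83, -0.01 to 0.47, 0.38 to 0.84, 0.25 to 0.55, -1.04 to -0.72 and -0.57 to -0.37, and the list counts from 11 to 16, 10 to 17, 11 to 17, 8 to 13, 3 to 12 and 5 to 10. The correlation of the sgRNA responses ran from 0.58 to 0.76, and turned to -0.0452 with the controls divided between the comparisons.

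Within 100 kb of Sim1 each of the 6 peak lists held 1 peak. At 50% reciprocal overlap shared peaks numbered 18 (SpCas9 hypothalamus promoter sgRNA with SaCas9 enhancer sgRNA), 21 (with Neuro2A promoter sgRNA), 15 (SpCas9 hypothalamus enhancer sgRNA with SaCas9 promoter sgRNA), 17 (with SaCas9 enhancer sgRNA) and 15 (with Neuro2A promoter sgRNA). Genes at an unadjusted p under 0.05 near peaks numbered 11, 36 (SpCas9 hypothalamus, promoter and enhancer sgRNA), 12, 7 (SaCas9), 6 and 32 (Neuro2A), and with DESeq2 and the block 2 calls (Klk7 and Rn7s6) lay near the SpCas9 hypothalamus enhancer sgRNA peaks. Recovered reads of 14.1 M in the shallowest library limit genes near 1 normalized count.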

Other observations

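The lists of reactive glial, liver, midbrain dopamine neuron and pineal genes and the age classes were chosen after the data were seen, and the scan of genomic regions was planned.

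Sim1 and Oxt were also averaged by age class within groups. Sim1 averaged 350 normalized counts at 3 to 4 months and 471 at 6 to 9 months in wild type, 139 and 283 in the Sim1 heterozygous group, and 181 and 312 with the promoter sgRNA, while the enhancer sgRNA group held 1 young animal at 287 and averaged 304 in the others. Oxt averaged 7735 at 3 to 4 months and 6007 at 6 to 9 months in wild type, 1245 and 604 in the Sim1 heterozygous group, and 2007 and 1226 with the promoter sgRNA. Whether the difference of Sim1 heterozygous from wild type depended on age class was tested as an interaction, and the lowest adjusted p was 0.707. Sim1 heterozygous means were below wild type in Sim1 and Oxt in both age classes.

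Reactive glial genes (24 measured, 6 of them in other lists) had a median log2 fold change of 0.79 in Sim1 heterozygous against wild type, with all 24 positive (camera's p = 0.000885 with an estimated correlation), of -0.66 with the promoter sgRNA (0.000829) and of -0.81 with the enhancer sgRNA (0.00111) against Sim1 heterozygous, 23 of 24 negative in each. These values of camera include the 7 genes that prompted the list, so they partly restate what was seen. Over the list mean, the two-sided exact permutation p of the same comparisons was 0.00794, 0.00476 and 0.0286 (0.0238, 0.0238 and 0.0571 adjusted over 6 comparisons). Without the 7 genes that prompted the list it was 0.00794, 0.00952 and 0.0857 (0.0286, 0.0286 and 0.171 adjusted), so the enhancer sgRNA comparison did not pass after adjustment. Genes of liver averaged 4.37 above the mean of all libraries in Sim1 heterozygous F_4 and at most 0.756 elsewhere, on the log2 scale. Midbrain dopamine genes were positive in 10 of 10 against wild type in the Sim1 heterozygous group (p = 0.0742 with an estimated correlation) and with the promoter sgRNA (0.0301), and in 9 of 10 with the enhancer sgRNA (0.0553). Pineal and retinal genes averaged 1.75 and 1.55 above the mean of all libraries in promoter sgRNA F_5 and M_3.

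Single libraries carried marks of other tissue or of unusual composition. Albumin (Alb) stood at 1557 normalized counts in Sim1 heterozygous F_4 and at most at 72.2 elsewhere, and prolactin (Prl) at 1773 in enhancer sgRNA F_2 and 1034 in Sim1 heterozygous F_3. Gm42418 took 9.07% of the reads in wild type F_2, 6.30% in Sim1 heterozygous F_4 and 4.90% in promoter sgRNA M_3, with a median of 1.06% over all libraries. Cortical genes averaged 2.06 above the mean of all libraries in promoter sgRNA M_3, on the log2 scale. Libraries correlated with each other at r between 0.954 and 0.990, with a mean of 0.976 within and of 0.976 between groups.

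No region of the genome passed a test for an excess of genes with an unadjusted p under 0.05. In 834 tests of 20 Mb windows over the 6 comparisons, the lowest adjusted p of Fisher's exact test was 0.113, for the window on chromosome 6 from 120 Mb with the promoter sgRNA against Sim1 heterozygous.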
